A study of Homo sapiens with 8 samples.

How the data were processed

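Formaldehyde-assisted isolation of regulatory elements with sequencing (FAIRE-seq) recovers DNA that is not tightly held by nucleosomes, so reads pile up over open chromatin. The assay was run on SUM-229PE, an established triple-negative breast cancer line grown from a pleural effusion, after its NEG and POS subpopulations had been isolated. Each subpopulation received the solvent DMSO or 30 nM trametinib, an inhibitor of the MEK kinases, for 24 h. The 4 groups held 2 libraries each, 8 in all. Fixed Drosophila S2 cells were added before nuclei were prepared, per the labels' protocols. Whether reads from those cells entered the scaling is not given in the sources used here, so a change of open chromatin over the whole genome could not be judged.

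The deposited values were a signal, the mean read coverage over each region, with a value per library, per the file headers and the values themselves. Each list gave regions 200 bp wide. The NEG list was the same for DMSO and trametinib, and so was the POS list. The submitters' processing notes named cutadapt 1.12, MACS2 2.1.2, bedtools 2.27.1 and the human build hg19 (GRCh37), with no role or order. The aligner, the read filters and the rule by which regions entered a list are not given in the sources used here. In every library 100.0% of the values, multiplied by the region width and by a single constant, came out whole within 0.05. If the signal was scaled to 1000000 reads, the constants corresponded to between 3.08e+07 and 4.66e+07 reads. They were sought only within a range of likely read numbers, so their size does not show that scaling. Another divisor per library would also give whole values. Scaling to 1000000 reads was therefore assumed here and is not stated by the authors. Under it, median depth ranged from 19.5 to 43.3 reads per base. Coverage is not a count of independent reads, so no count model was used.

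Columns were matched to groups by their headers, in which the treated columns carry GSK where the labels say trametinib. Within a group the headers show a column without a number and a column numbered 2, called the unnumbered library and the library numbered 2 here. Where a library was left out, the unnumbered one is named replicate 1 and the one numbered 2 replicate 2. These are names only, since the headers do not tie a column to a replicate of the labels. Nothing in the sources used here says that the 2 libraries of a group came from separate cultures. P-values thus rest only on the spread between these libraries, which may be technical and which the fits below pool over regions. Values for DMSO and trametinib, and for NEG and POS, came from separate tables, each scaled library by library.

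NEG and POS regions were joined with bedtools 2.31.1 where they overlapped by at least 1 bp. The overlap was set beside 100 placements of the POS regions at random positions between the outermost regions of the same chromosome, and 100 placements within 50 kb of their own positions. Since both treatments share a list, this overlap describes the lists and not DMSO alone. Trametinib was compared with DMSO within each subpopulation by limma 3.58.1 in R 4.3.3 on log2(signal + 1), with a prior variance that followed the mean and Benjamini-Hochberg adjustment at 0.05. The tests were two-sided. Limma draws the variance of each region toward that prior. The SE and p-value of a region can thus rest mostly on regions of like signal and not on its own 2 libraries per group. Log2 changes are on that scale and understate the change of regions with low signal. POS was compared with NEG at the shared regions in the same way, once under DMSO and once under trametinib, and an interaction term compared the trametinib changes. Regions found in only 1 list had no value for the other subpopulation and were not tested between them. Chromosome shares were compared by Fisher's exact test, two-sided, with adjustment over 24 chromosomes. Regions are not replicates, so those p-values describe these lists.

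The designs of the overlap, the trametinib comparisons, the interaction and POS against NEG under DMSO were fixed before the data were examined. So were the alternatives and the naming rule. POS against NEG under trametinib, the tests by chromosome and the placements within 50 kb were not among those designs. The alternatives covered pseudocounts, a signal filter, centring each library on its median, quantile normalization, a threshold of 0.1, the replicate block and leaving out each library. Scaling each library to a common median, a fit without the mean-variance trend, and centring combined with another choice were added after seeing the data. By the rule, named regions were the 3 with the highest mean DMSO signal among those found in 1 list. For a tested comparison they were the 3 largest changes per direction past the threshold with a mean above the median of all regions. Where the values as deposited left fewer than 3 in a direction, regions past the threshold after centring are also named, a step added after seeing the data. Regions on chromosome Y were left out of the naming.

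The limma step was tested on simulated data with the real means and library medians. The real spreads were shuffled among regions, and noise was drawn independently for each library. Links of spread to mean, and of same-numbered libraries to each other, were thus absent. Simulated falls of 1.2 also exceed what log2(signal + 1) allows at the median signal of any library. The shares below describe the fit on such data and not its power here. For trametinib in NEG, over 4594 regions, it recovered 1% of simulated log2 changes of 0.6 and 95% of those of 1.2. After centring these shares were 67% and 95%. For trametinib in POS, over 7846 regions, they were 0% and 99%, and 29% and 86% after centring. False calls numbered 5 in NEG and 2 in POS after centring, and 0 in both before it.

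No annotation of the build the files use was given, so regions are named by chromosome, start and end as the files list them on hg19. Genes near the regions, promoter shares, the 12 gene lists and the 21 motifs planned were not analysed here. ACKR3, EPCAM, VIM and DUSP6, which were to be looked up in any case, were likewise not analysed here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.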

Results

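Open chromatin was profiled by FAIRE-seq in the NEG and POS subpopulations of the SUM-229PE breast cancer line, with DMSO or with 30 nM trametinib for 24 h. Each of the 4 groups had 2 libraries. The NEG list held 4594 regions and the POS list 7846. Median signal differed widely between the libraries of a group. In NEG it was 1.01 and 0.563 under DMSO, for the unnumbered library and the library numbered 2, and 0.819 and 0.535 under trametinib. In POS it was 0.990 and 0.534 under DMSO and 0.807 and 0.667 under trametinib. The order followed the inferred read number only in NEG under trametinib, at 4.16e+07 for the unnumbered library against 3.64e+07. Elsewhere the library numbered 2 had lower signal but more inferred reads. These were 4.25e+07 against 3.08e+07 in NEG under DMSO. In POS they were 4.41e+07 against 4.37e+07 under DMSO and 4.66e+07 against 4.40e+07 under trametinib. No region was listed at 0 in any library.

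Open regions were unevenly spread, and a single stretch of chromosome 8 held the most in both lists. Between 126 and 127 Mb of that chromosome lay 37 NEG regions and 53 POS regions, of which 25 were shared. Their median signal was 2.49 and 1.51 in the NEG DMSO libraries and 2.37 and 1.501 in the POS DMSO libraries, above the medians of all regions given above. The next densest 1 Mb stretch of the NEG list, on chromosome 19 from 46 to 47 Mb, held 23 regions. That of the POS list, on chromosome 17 from 73 to 74 Mb, held 26.

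The first comparison asked how far the open regions of NEG and POS cells coincide. The lists shared 2099 regions, 45.7% of the NEG list and 26.8% of the POS list. Of these, 1709 (81.4%) began within 50 bp of each other. A further 2495 regions stood in the NEG list alone and 5747 in the POS list alone. Random placement gave a mean overlap of 6.58 regions (range 1 to 14), and placement within 50 kb gave 25.1 (range 15 to 41). Shared regions had higher signal than the rest of the same list. In the unnumbered NEG DMSO library the median was 1.16 for shared regions and 0.905 for regions of the NEG list alone. In the unnumbered POS DMSO library these were 1.204 and 0.915. Regions of the NEG list alone lay a median of 58.4 kb from the nearest POS region, and 330 of them (13.2%) within 10 kb. For regions of the POS list alone the median distance to the nearest NEG region was 127 kb, with 396 (6.89%) within 10 kb. The lists differ in length, and a region missing from a list has no value there, so its signal in the other subpopulation is not known.

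Among regions of the NEG list alone, the highest mean DMSO signal was on chromosome 11 from 71484088 to 71484288, at 3.67 ± 1.61 (SD, n = 2). Next came chromosome 9 from 18543550 to 18543750, at 3.13 ± 1.47 (SD, n = 2), and chromosome 8 from 126692544 to 126692744, at 3.04 ± 1.45 (SD, n = 2). Among regions of the POS list alone, the highest was on chromosome 9 from 21294351 to 21294551, at 2.80 ± 1.87 (SD, n = 2). It was followed by chromosome 8 from 126155683 to 126155883, at 2.72 ± 0.356 (SD, n = 2), and from 126186938 to 126187138, at 2.69 ± 1.02 (SD, n = 2). Of these 6 regions, 3 lay in the dense stretch of chromosome 8. The order among them was not tested.

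Whole chromosomes contributed differently to the regions found in 1 list. These tests by chromosome were not among the designs fixed beforehand. Chromosome 16 held 222 regions of the NEG list alone (8.90%) and 136 of the POS list alone (2.37%), an odds ratio of POS over NEG of 0.248 (Fisher's exact test, adjusted p = 2.28e-35). Chromosome 7 went the other way, with 109 (4.37%) and 582 (10.1%), an odds ratio of 2.47 (adjusted p = 8.29e-19). Chromosome 14 held 27 (1.08%) and 246 (4.28%), an odds ratio of 4.09 (adjusted p = 2.22e-15). Of 24 chromosomes, 8 had an adjusted p under 0.05. The signal at shared regions went the same way in all 4 library pairs on chromosomes 7, 9, 14 and 16, and the other way on chromosome 6. On chromosomes 8, 17 and 19 the sign differed between pairs. After centring each library pair, the chromosome 16 median of log2 POS over NEG was -0.38, -0.38, -0.46 and -0.35 in the 4 pairs, and 112 of 122 shared regions were lower in POS. On chromosome 7 it lay between 0.21 and 0.30, and 111 of 129 shared regions were higher in POS. On chromosome 14 it lay between 0.22 and 0.46, with 28 of 34 higher. Chromosome 9 (odds ratio 2.47, adjusted p = 4.59e-10) had 0.43 and 0.56 in the unnumbered pairs and 0.16 and 0.05 in the pairs numbered 2. Chromosome 8 (odds ratio 0.665, adjusted p = 1.34e-05) lay between -0.12 and 0.01, and chromosome 17 (odds ratio 0.772, adjusted p = 0.0263) between -0.03 and 0.06. Chromosome 6 had more regions in the POS list alone (odds ratio 1.38, adjusted p = 0.0223), while its shared regions had medians between -0.23 and -0.11 in the 4 pairs, and 62 of 102 were lower in POS. Chromosome 19 had an odds ratio of 0.337 (adjusted p = 3.53e-18), but its medians were -0.74 and -0.79 in the unnumbered pairs and 0.01 and 0.05 in the pairs numbered 2.

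**Figure D1:**
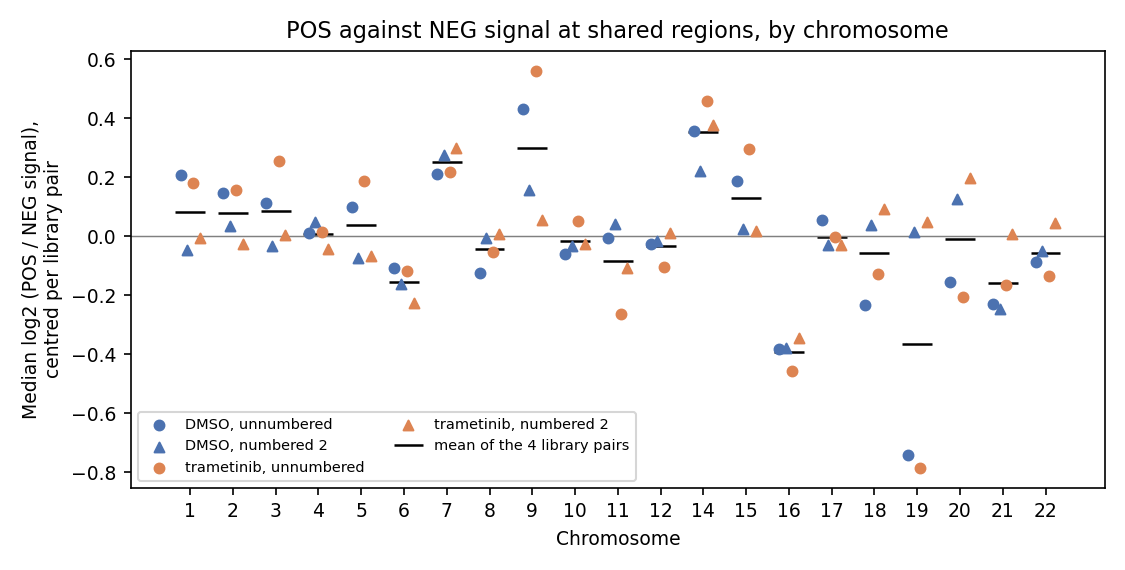
Median log2 ratio of POS over NEG signal at shared regions (y axis, centred within each library pair) for the 21 chromosomes with at least 10 shared regions (x axis). Points are the 4 library pairs, circles unnumbered and triangles numbered 2, and black lines their means: chromosome 16 sits between -0.46 and -0.35 in all 4 pairs, while chromosome 19 splits by column. Other chromosomes split as well, such as chromosome 20, at -0.16 and -0.21 in the unnumbered pairs and 0.12 and 0.20 in those numbered 2.

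At the 2099 shared regions, limma on the values as deposited called 0 regions between POS and NEG under DMSO at an adjusted p of 0.05, with 6 higher and 0 lower in POS at an unadjusted p under 0.05. Under trametinib, a comparison not among the designs fixed beforehand, it called 11, of which 7 were higher and 4 lower in POS. Centring each library on its median gave 50 under DMSO, 26 higher and 24 lower, and 113 under trametinib, 67 higher and 46 lower. After centring, the largest difference under DMSO among called regions with signal above the median was on chromosome 6 from 35779006 to 35779206. Its signal was 0.574 ± 0.146 (SD, n = 2) in NEG and 2.47 ± 1.32 (SD, n = 2) in POS, a log2 difference of 1.07 ± 0.16 (SE). Limma gave an adjusted p of 4.71e-08 after centring, and between 3.62e-11 and 0.999982 over the alternatives. The other 2 regions higher in POS lay on the same chromosome, from 34577480 to 34577680 (2.71-fold higher mean) and from 36409232 to 36409432 (2.40-fold). Lower in POS were chromosome 20 from 52390449 to 52390649 (2.63-fold higher in NEG), and chromosome 8 from 126322013 to 126322213 (2.40-fold) and from 129527087 to 129527287 (2.15-fold). Chromosome 16 held 9 of the 24 regions lower in POS and 0 of the 26 higher.

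Under trametinib, the only region named from the values as deposited was on chromosome 3 from 132036475 to 132036675, with a signal of 0.371 ± 0.140 (SD, n = 2) in NEG and 1.64 ± 0.324 (SD, n = 2) in POS. Its log2 difference was 0.94 ± 0.25 (SE), with a limma adjusted p of 0.0446. After centring, a step beyond the rule fixed beforehand, the called regions above the median signal with the largest differences under trametinib were again that on chromosome 6 from 35779006 (4.17-fold higher in POS), then this chromosome 3 region (4.42-fold on the values as deposited) and chromosome 20 from 49378357 to 49378557 (3.53-fold). In the other direction were chromosome 8 from 116251376 to 116251576 (2.75-fold higher in NEG), chromosome 20 from 52390449 (2.07-fold) and chromosome 19 from 58987453 to 58987653 (2.36-fold). Apart from chromosome 3, these had an adjusted p between 0.0547 and 0.999 on the values as deposited. After centring, 16 of the 26 regions higher in POS under DMSO were also called higher under trametinib, where independent lists would share 0.83. For regions lower in POS it was 7 of 24, against 0.526. These chance values take the DMSO and trametinib libraries as independent, which was not established. The direction was the same under trametinib for 25 of the 26 and for 24 of the 24. Counts and directions rested on single libraries. Under DMSO after centring they were 1 higher and 1 lower without NEG replicate 1, 14 and 13 without NEG replicate 2, 3 and 0 without POS replicate 1, and 41 and 83 without POS replicate 2. The 7 higher and 4 lower under trametinib as deposited became 22 and 5 without NEG replicate 1, 4 and 29 without NEG replicate 2, and 0 without either POS library. After centring, the 67 and 46 became 100 and 135 without POS replicate 2.

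The next comparison asked which regions opened or closed in NEG cells during 24 h of trametinib. On the values as deposited, limma called 0 of 4594 regions, with 10 higher and 87 lower at an unadjusted p under 0.05. The median log2 change was -0.09, and its sign rested on single libraries: it was 0.10 without DMSO replicate 1 (6 higher and 8 lower at the unadjusted threshold), 0.04 without trametinib replicate 2 (13 and 0), -0.29 without DMSO replicate 2 (3 and 419) and -0.22 without trametinib replicate 1 (2 and 8). After centring, 68 regions were higher and 122 lower under trametinib, and after quantile normalization 275 were higher and 298 lower. The 3 largest rises after centring with signal above the median all lay on chromosome 8. The region from 117574894 to 117575094 had a signal of 0.399 ± 0.0245 (SD, n = 2) under DMSO and 1.37 ± 0.0145 (SD, n = 2) under trametinib, 3.42-fold higher. Its centred log2 change was 0.84 ± 0.11 (SE), with a limma adjusted p of 1.66e-11, between 2.54e-20 and 0.999974 over the alternatives. The SDs above are of the values as deposited and do not show the spread after centring. The SE is limma's, which draws on regions of like signal. As deposited the log2 change was 0.76 ± 0.32 (SE), with a limma adjusted p of 0.999973. The region from 116430548 to 116430748 had 0.813 ± 0.0230 (SD, n = 2) and 1.62 ± 0.124 (SD, n = 2), and the region from 122184782 to 122184982 had 0.796 ± 0.159 (SD, n = 2) and 1.49 ± 0.0241 (SD, n = 2). The largest falls by the same rule were on chromosome 8 from 100507577 to 100507777 (2.36-fold lower mean), chromosome 1 from 218382813 to 218383013 (2.78-fold) and chromosome 16 from 19103583 to 19103783 (2.85-fold). Signal was lower under trametinib in both library pairs at each of these 3. All 6 regions stood in the NEG list alone.

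Of the 190 NEG regions called after centring, 161 stood in the NEG list alone. Most had low signal, since only 9 of the 68 higher and 28 of the 122 lower regions lay above the median. Shared regions made up 7.35% of those that were higher and 19.7% of those that were lower, against 45.7% of the whole list (Fisher's exact test over regions, adjusted p = 1.90e-11 and 3.27e-09). How regions entered the list is not known, so this test does not separate a drug effect from how the list was built. On the values as deposited, both trametinib libraries lay above both DMSO libraries at 191 regions (4.16%) and below them at 621 (13.5%). After scaling to a common median these were 1025 (22.3%) and 1228 (26.7%). Exchangeable libraries would give 16.7% per direction. As deposited the library medians differed too widely for that, and after scaling the list may still have been chosen by treatment. The 16.7% is thus no chance level for these shares. Among the regions set apart in this way, the means differed by at least 2-fold at 17 higher and 206 lower regions as deposited, and at 51 and 100 after scaling. The balance of rises and falls after centring turned on single libraries: 1 higher and 11 lower without DMSO replicate 1, 178 and 118 without DMSO replicate 2, 1 and 0 without trametinib replicate 1, and 6 and 35 without trametinib replicate 2. On the values as deposited the count of 0 became 20 without DMSO replicate 2.

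**Figure D2:**
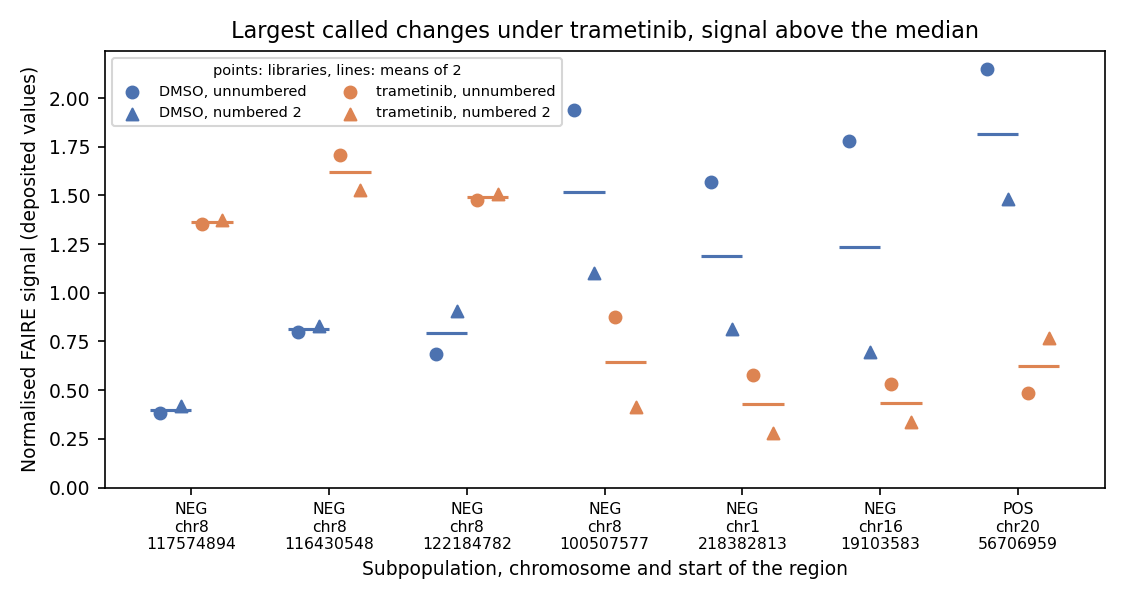
Deposited FAIRE signal (y axis) in each library at the 6 NEG regions and 1 POS region with the largest log2(signal + 1) changes under trametinib among those called after centring with signal above the median of their list (x axis). Points are libraries, circles unnumbered and triangles numbered 2, and lines are means of 2: the first NEG region goes from 0.399 under DMSO to 1.37 under trametinib.

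In POS cells, limma called 8 of 7846 regions under trametinib on the values as deposited, all higher and all outside the shared regions. Their signal under DMSO lay between 0.0315 and 0.179, below the 5th percentile of both DMSO libraries (0.442 and 0.276). Under trametinib it lay between 0.404 and 0.717. Their mean signal was below the median of the list, so none met the naming rule's signal requirement. Those named here were chosen after their values were seen. How regions entered the POS list is not known. Regions so low under DMSO may have entered it through their trametinib signal, so these rises are not independent evidence of a drug effect. Without the mean-variance trend, a fit added after seeing the data, limma called 0 regions. The largest rise on log2(signal + 1) was on chromosome 4 from 106132141 to 106132341, from 0.124 ± 0.0235 (SD, n = 2) to 0.632 ± 0.121 (SD, n = 2), a log2 change of 0.54 ± 0.11 (SE) with a limma adjusted p of 0.00170. Its mean was 5.11-fold higher. Chromosome 6 from 16406788 to 16406988 went from 0.157 ± 0.0302 (SD, n = 2) to 0.630 ± 0.0441 (SD, n = 2), 4.01-fold higher. Chromosome 15 from 74008967 to 74009167 went from 0.0645 ± 0.0466 (SD, n = 2) to 0.447 ± 0.0564 (SD, n = 2). At 6.94-fold this was the largest ratio of means among the 8. Centring gave 4 higher and 5 lower regions, and 0 of the 8 were among them. Quantile normalization gave 122 higher and 198 lower, and scaling to a common median 148 higher and 72 lower, so the balance of directions in POS turned with the scaling. The only region with signal above the median called after centring was on chromosome 20 from 56706959 to 56707159, at 1.81 ± 0.474 (SD, n = 2) under DMSO and 0.625 ± 0.199 (SD, n = 2) under trametinib, 2.90-fold lower. At its NEG counterpart the signal was 1.54 and 0.975 under DMSO and 1.33 and 0.851 under trametinib. The direction turned on single libraries. Without DMSO replicate 1 the 8 became 79 higher and 3 lower, and without DMSO replicate 2 they became 82 higher and 472 lower, or 446 higher and 81 lower after centring. The count was 0 without trametinib replicate 1 and 1 without trametinib replicate 2.

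**Figure D3:**
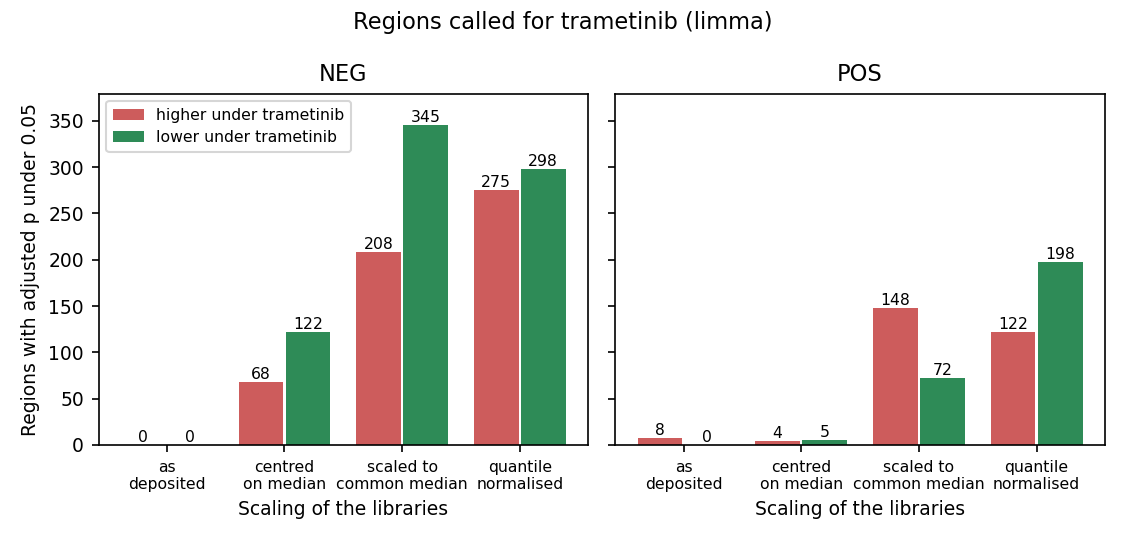
Number of regions with a limma adjusted p under 0.05 (y axis) that were higher or lower under trametinib in NEG and POS, for 4 ways of scaling the libraries (x axis). Values as deposited gave 0 regions in NEG and 8 in POS, and quantile normalization gave 573 and 320.

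Whether trametinib acted differently in NEG and POS cells was tested by the interaction term at the 2099 shared regions. Limma called 0 regions, with 3 positive and 1 negative at an unadjusted p under 0.05, and 0 again after centring, with 33 and 24. The lowest adjusted p was 0.699, and 0.237 after centring. Quantile normalization called 3 regions, leaving out NEG DMSO replicate 2 called 1, and leaving out POS trametinib replicate 2 after centring called 2. Calls at shared regions thus turned on the setting, and regions found in 1 list alone could not enter this test. Across shared regions the log2 changes in NEG and POS correlated weakly, with Pearson's r of 0.18 and Spearman's rho of 0.16, and with r between 0.07 and 0.14 for single library pairs. This is a correlation across regions, which are not independent replicates. Of the 24 shared regions called lower in NEG after centring, 15 were lower and 9 higher in POS. Of the 5 called higher in NEG, 3 were higher and 2 lower in POS.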

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

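Centring with another pseudocount, with the replicate block or with a library left out, scaling to a common median, and the fit without a mean-variance trend were chosen after seeing the data. Libraries of a group differed widely in median signal, and settings that removed this difference called more regions in most comparisons. For trametinib in NEG, 0 regions became 190 after centring, 573 after quantile normalization, 553 after scaling to a common median and 446 after centring with a pseudocount of 0.1. For trametinib in POS, 8 became 320 after quantile normalization, 220 after scaling, 24 after centring with a pseudocount of 0.1, 13 at a threshold of 0.1, and 0 both above the median signal and without the mean-variance trend. For POS against NEG under DMSO, 0 became 50 after centring, 93 after quantile normalization, 88 after scaling and 83 after centring with a pseudocount of 0.1. Under trametinib, 11 became 113, 174, 156 and 125 in that order, 0 above the median signal and 5 without the trend. The interaction went from 0 to 3 after quantile normalization and 1 after scaling. For these settings the cause was not tested.

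With the replicate block on the values as deposited, counts were 608 in NEG (62 higher, 546 lower) and 79 in POS (55 higher, 24 lower). They were 93 for POS against NEG under DMSO, 62 under trametinib and 1 for the interaction. Centring and the replicate block together gave 708 (312 higher, 396 lower), 868 (542 higher, 326 lower), 130 and 152 for the first 4 of these. Same-numbered libraries deviated together across regions (r = 0.50 in NEG and 0.53 in POS), but with 2 numbers and no label that ties them this does not establish pairs.

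Leaving out a library gave 0 to 20 regions in NEG, 0 to 554 in POS, 0 under DMSO, 0 to 33 for POS against NEG under trametinib and 0 to 1 for the interaction. After centring, without DMSO replicates 1 and 2 and trametinib replicates 1 and 2 in turn, NEG gave 12, 296, 1 and 41 and POS 0, 527, 9 and 10. Without NEG replicates 1 and 2 and POS replicates 1 and 2 in turn, POS against NEG gave 2, 27, 3 and 124 under DMSO and 12, 61, 70 and 235 under trametinib. The interaction then gave 0 to 2. With a library left out, the lone library of its group is assumed to vary like the others. The shared regions numbered 1125 among regions above the median DMSO signal, where both lists are shorter by construction, and 1678 with lists of the same length. The correlation of trametinib changes was 0.14 above the median signal. No direction reversed among 22 results for 20 named regions, over the alternatives run for each. These regions were picked for large changes in the same libraries, so a kept direction was likely beforehand and is no independent check. Of the 22, 5 passed the threshold after centring both with all libraries and with each left out in turn. Alternatives for gene lists, promoter shares and motifs were not run.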

Other observations

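The tests below were all chosen after the patterns had been seen. Across 2099 shared regions, the log2 differences between POS and NEG under DMSO and under trametinib correlated with r of 0.65. Part of this went with the column number: r was 0.68 and 0.47 between libraries of the same number, and 0.28 and 0.37 between libraries of different numbers. Trametinib changes were also set out for chromosomes 8 and 19, the only ones tested. The adjustment covers their 16 tests and not all chromosomes. After scaling to a common median, chromosome 8 held 61 of the 460 NEG regions among the 10% with the highest changes (odds ratio 1.52, Fisher's exact test adjusted over 16 tests, p = 0.0129) and 88 of the 785 in POS (odds ratio 1.69, adjusted p = 0.000120). With a pseudocount of 0.1 in place of 1, these were 1.21 (adjusted p = 0.351) and 1.47 (adjusted p = 0.00832). In NEG, chromosome 8 also held 54 of the 460 regions with the lowest changes (odds ratio 1.30, adjusted p = 0.151), so no direction is drawn for NEG. Chromosome 19 held 1 of the 785 POS regions with the highest changes (odds ratio 0.029, adjusted p = 4.11e-12), and 31 of those with the lowest (odds ratio 1.03). In NEG it held 28 of the 460 with the highest (odds ratio 0.82, adjusted p = 0.448) and 10 of those with the lowest (odds ratio 0.26, adjusted p = 3.60e-06). The POS over NEG signal of chromosome 19 went with the column number, as given below. Whether library composition produced these shares of trametinib changes was not tested.

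Signal differed between NEG and POS along chromosomes 7, 14 and 16, with the same sign in 4 of 4 library pairs on each. The sign also held in 4 of 4 pairs on chromosomes 6, 9 and 15. Chromosome 15, with medians between 0.018 and 0.30, did not differ in counts of regions found in 1 list (odds ratio 1.18, Fisher's exact test, adjusted p = 0.538). Chromosomes 7, 14 and 16 were picked after the pairs had been seen. Their agreement therefore does not decide on the composition of single libraries. On chromosome 16 all 5 pieces of 20 Mb with at least 10 shared regions were lower in POS (-0.48 to -0.25), and on chromosome 7 all 8 were higher (0.10 to 0.31). Different chromosome copy numbers in NEG and POS cells are a candidate explanation: over 21 chromosomes, the ratio of region counts found in 1 list followed the signal ratio at shared regions (r = 0.90, rho = 0.62, permutation p = 1e-05 and 0.003), and r was 0.87 without chromosome 19, 0.81 without chromosomes 14 and 16, 0.70 without all 3, and 0.73 (rho = 0.48) with the signal of the libraries numbered 2 alone. Both measures come from the same libraries, the smallest p that 100000 permutations give is 1e-05, and a chromosome-wide difference in chromatin was not tested, so copy number stays a hypothesis. Chromosome 6, which is among the 21, went against a copy number difference of the whole chromosome. Its odds ratio was 1.38 toward POS, while its shared regions were lower in POS in 4 of 4 pairs (mean -0.15). Its medians were -0.34 from 20 Mb and 0.22 from 40 Mb. Regions found in 1 list were not counted by piece, so a difference in part of that chromosome was not tested. For chromosome 19 the mean was -0.76 in the unnumbered libraries and 0.031 in those numbered 2, at a like size in both treatments, so the shift followed the unnumbered libraries as a set; this is consistent with a composition that differs between the unnumbered libraries and those numbered 2.

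The order of rows showed 3 runs in both lists. Borders were set on the unnumbered libraries and judged on those numbered 2. In NEG, 93.1% of the 950 regions in the second run were lower under trametinib and 98.6% of the 499 in the third run were higher. In POS these shares were 98.4% of 703 and 90.5% of 1495. The lists may stack regions found in both treatments, then in DMSO only, then in trametinib only. Shared regions made up 17.8% and 19.2% of the second and the third NEG run, against 58.3% of the first. Of the 122 NEG regions called lower after centring, 119 lay in the second run, where 18.5% of them were shared, and of the 68 called higher, 64 lay in the third run, where 7.81% were shared. Against their own run the falls were thus not short of shared regions (18.5% against 17.8%). For the rises the share was lower (7.81%, 5 of 64, against 19.2%), but this was not tested. Most called rises had low signal and shared regions had higher signal, and the comparison was not matched for signal. If all libraries helped to choose the regions, the agreement of calls with runs is not independent evidence of a drug effect.

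Regions called for trametinib after centring were set beside the other splits of the 4 libraries, of which there are 3 in all, too few for a share under 0.05. In NEG the treatment gave 190 regions and the split by column number 0, the highest of the other splits. At an unadjusted p under 0.05 these were 677 and 472. After quantile normalization they were 573 and 0, and 1084 and 225 unadjusted. In POS the treatment gave 9 and the split by column number 11, while quantile normalization gave 320 and 12. Whether differences between the unnumbered columns and the columns numbered 2 are as large as those between treatments stays open in both subpopulations. In NEG the treatment was ahead in each of these counts, but the list itself may have been chosen by treatment, and in POS the order turned with the scaling. On the values as deposited the split by column number called 1773 regions in NEG and 549 in POS. After centring it called 0 and 11, so most of these calls went with the difference in median signal between the columns.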
